A study of Mus musculus with 17 samples.

How the data were processed

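The series measured polyadenylated RNA in the frontal cortex of male FVB/N mice. The mice carried a Tet-off pair of transgenes: a CamK driver, which makes a transactivator in forebrain excitatory neurons, and a transgene in which that transactivator switches on the microRNA miR-211. Doxycycline blocks the transactivator and so switches miR-211 off. Per the labels, 6 libraries came from mice with the driver alone (Ct), 7 from mice with both transgenes (dTg), 3 from mice with both transgenes given doxycycline for 4 days (dTgDox), and 1 from a mouse with the miR-211 transgene and no driver (NTg). Libraries were made with the NEBNext kit for polyA RNA and read from 1 end on a NextSeq instrument. The labels name 2 flow cells but do not assign libraries to them, so a difference between flow cells could not be tested. There was no doxycycline-treated Ct group, so an effect of doxycycline itself and of the loss of miR-211 were not separable by design.

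TopHat2 and DESeq are named in the submitters' processing notes. Their versions, the genome build, the annotation and the quantifier are not given in the sources used here. Each deposited file holds one value per Ensembl gene for 46073 genes, and its header line gives only a name for the library. The values behave as FPKM (fragments per kilobase of transcript, scaled to a fixed number of mapped reads): the deposited FPKM of single-exon genes step by a constant amount divided by gene length, and the totals per library were 595615 to 695518 rather than whole read counts. Read counts were not used here. The size of a 1-read step in 6051 single-exon genes gave a relative depth per library of 0.87 to 1.25 and a depth of about 21.2 to 30.2 M reads; these are estimates, so no counting intervals were computed from them. Gene symbols and coordinates were taken from GENCODE M21 (GRCm38) by Ensembl identifier, which gave a symbol to 45139 identifiers and none to 934. Coordinates are those of that annotation.

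All files were compared with each other value by value. The file labelled NTg replicate 1 and that labelled dTg replicate 1 held identical values for all 46073 genes, 24415 of them above 0, and no other pair was identical. The header line of the NTg file also names the dTg library. The 17 files therefore hold 16 distinct libraries. The shared library was counted once, in dTg as replicate 1, and the comparison of NTg with any group was left out because the NTg file analysed holds no values of its own.

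The analysis used limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), for genes with at least 0.5 FPKM in at least 3 of the 16 libraries. One mean per group was fitted, with empirical Bayes moderation with a trend on mean level and robust to outlying genes. The comparisons were dTg with Ct, dTgDox with dTg, and dTgDox with Ct. P-values were two-sided and adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. A count model had been planned and was replaced because the values were not counts. The added 0.5 pulls fold changes of genes with low FPKM toward 0. Fold changes are log2 values from this fit, with the standard error (SE) of the fit, and levels are mean FPKM ± SD over all libraries of a group.

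Groups of genes were tested with camera at a preset correlation between genes of 0.01, for 39 lists with at least 5 measured members, and adjusted over the lists of one comparison. Each test was repeated with camera's estimated correlation and with fry. Camera asks whether a list moved more than other genes; fry asks whether its genes moved, on balance, one way. Genes with a match to the miR-211 seed were taken from the longest annotated 3'UTR of each gene: 1085 measured genes held an 8mer site, and 8689 without the 6mer core served as the comparison. The lists, the named-gene rule, the comparisons and the first set of alternatives were fixed before the data were examined. Leaving out each library in turn was among them; giving the fit on the 15 libraries without the one shared by dTg and NTg beside the fit on all 16 was chosen afterwards. Also chosen afterwards were the fit on 13 libraries, the alternatives of pseudocount, stricter filter, scaling, quality weights, residual component and gene class, the lists of cerebellar genes and of genes of plaque-associated microglia, and a shuffled-seed control.

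Named genes followed a rule. For each comparison these were the 12 highest and 12 lowest fold changes among genes passing the threshold with a mean log2 level of at least 1 and an informative symbol. With fewer than 10 such genes, the smallest unadjusted p-values filled the set to 10. Mir211, Trpm1, Camk2a, Chrna7, Ache and Tgfbr2, and genes at a reported insertion site of a Camk2a driver line, were always included. So were the 4 members with the smallest p-values in each list that passed and in 5 lists chosen beforehand. Some genes that the rule names are not reported here. Genes outside the rule are marked as chosen after their values were seen.

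The fit was tested on simulated data by adding log2 changes of 0.5, 1 or 2 to 200 genes with a mean log2 level of at least 1. The simulated noise was independent between genes and held no outlying library, so the shares may not carry over to the real data. Of the 67 genes with an added log2 change of 1 it called 82.1% for dTg with Ct, 74.6% for dTgDox with dTg and 77.6% for dTgDox with Ct. At an added log2 change of 0.5 these shares were 40.9%, 33.3% and 30.3%. Without the shared library the shares at 0.5 were 74.2%, 59.1% and 63.6%. Alternatives covered the pseudocount, the low-value filter, scaling between libraries, array-style quality weights, a residual component, a replicate block, the libraries included, and leaving out each library in turn. P-values measure the spread between samples; the labels do not say that each sample is a separate animal. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.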

Results

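RNA abundance was measured in the frontal cortex of mice with transgenes for excess miR-211 in forebrain neurons, of driver-only mice, and of miR-211 mice given doxycycline for 4 days. The drug is meant to stop miR-211 production, which no value here measured. miR-211 is a microRNA whose gene, Mir211, lies in an intron of Trpm1, and the series title links it to cholinergic imbalance and epileptiform activity. The groups were Ct (n = 6), dTg (n = 7) and dTgDox (n = 3), in 16 distinct libraries. The library deposited under both dTg replicate 1 and NTg replicate 1 was counted in dTg. Estimated depth was 21.2 to 30.2 M reads, relative depth 0.87 to 1.25, and 15762 to 16085 genes per library had at least 1 FPKM. Across genes, the correlation of log2 values between pairs of the 15 other libraries was 0.924 to 0.961, and that of the doubly deposited library with them was 0.834 to 0.853. Correlations were 0.956 to 0.961 among the dTgDox libraries, 0.943 to 0.960 among Ct and dTg replicates 2 to 7, and 0.924 to 0.946 between these and dTgDox. Genes are not independent replicates, so these values describe similarity only.

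The transgene itself could be checked only in part. Mir211 (ENSMUSG00000065585, chromosome 7, 64205806 to 64205911) was listed at 0 in every library but dTg replicate 2, at 21.6 FPKM, and dTg replicate 5, at 24.8 FPKM. PolyA libraries do not capture mature microRNAs, so these values say little about the amount of miR-211. Trpm1 (ENSMUSG00000030523, chromosome 7, 64153835 to 64269775), the host gene, a cation channel of retina and melanocytes, had 0.04 to 0.40 FPKM in all libraries. Neither gene passed the filter on low values. The driver uses the promoter of Camk2a (ENSMUSG00000024617, chromosome 18, 60925618 to 60988152), a kinase of excitatory synapses. Its level was 758 ± 115 FPKM (SD, n = 6) in Ct, 688 ± 340 (SD, n = 7) in dTg and 714 ± 51.7 (SD, n = 3) in dTgDox. The doubly deposited library had 28.3 FPKM of Camk2a, and dTg replicates 2 to 7 averaged 798 ± 192.

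The comparison of dTg with Ct asked what excess miR-211 does to cortical RNA. No gene passed the threshold in limma among 19186 tested, so no single transcript was shown to respond. Acetylcholine signalling, the TGF-beta pathway and immediate-early genes of active neurons, the systems closest to the study's subject, each held 0 called genes. Lists for neurons and their peptides lay slightly lower and those for oligodendrocytes, choroid plexus and interferon responses slightly higher, but none of these shifts held when the correlation between genes was estimated. The doubly deposited library sits in this comparison, and its mean log2 level of cerebellar markers was 7.085, against 2.359 or less in all others.

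At an unadjusted p under 0.05, limma gave 480 genes where chance alone would give 959, and no other gene-level tool was run. Without the doubly deposited library the count was again 0 in limma, with 607 at the unadjusted level and 953 given by chance. The smallest adjusted p was 0.082, for Gm26244 (chromosome 18, 10150977 to 10151140), a gene of unknown function chosen after its values were seen. It was listed at 0 in all Ct libraries and had 1.26 to 16.4 FPKM in dTg. Without the doubly deposited library its adjusted p was 0.31. In dTgDox it had 1.21 to 6.43 FPKM, and against Ct it was called there, with a limma difference of 2.67 and an adjusted p of 0.0074. Among named genes, Apobec3 (ENSMUSG00000009585, chromosome 15, 79891659 to 79915906), a cytidine deaminase that restricts retroviruses, had 2.19 ± 0.56 FPKM (SD, n = 6) in Ct and 4.11 ± 0.70 (SD, n = 7) in dTg. All 7 dTg libraries lay above all 6 Ct libraries, the fitted difference was 0.79 (SE 0.15), and the adjusted p was 0.44. Cspp1, a centrosome and cilium protein, had a difference of 0.39 and an adjusted p of 0.78. Another 7 with the smallest p-values, Lbhd1, Mamstr, Mrpl10, Nudt1, Utp18, Zcchc7 and Zfp551, had differences of -0.57 to 0.61 and an adjusted p of 0.96.

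Genes of acetylcholine signalling did not pass the test either. Ache (ENSMUSG00000023328, chromosome 5, 137287519 to 137294466), the enzyme that breaks down acetylcholine at the synapse, had 29.5 ± 4.71 FPKM (SD, n = 6) in Ct and 29.3 ± 2.37 (SD, n = 7) in dTg. Its difference was 0.00 with an adjusted p of 1.0. Chrna7 (ENSMUSG00000030525, chromosome 7, 63098692 to 63212569), the alpha7 nicotinic receptor subunit, had 6.08 ± 0.94 FPKM in Ct and 5.25 ± 1.87 in dTg, a difference of -0.27 with an adjusted p of 0.96. Without the doubly deposited library, at 1.879 FPKM, the Chrna7 difference was -0.07. Tgfbr2 (ENSMUSG00000032440, chromosome 9, 116084293 to 116175360), a receptor for TGF-beta, had 3.87 ± 0.27 and 3.92 ± 0.77 FPKM, a difference of 0.00. Chrm2, the muscarinic autoreceptor, and Bcl2, a survival factor with miR-211 among its reported regulators, had differences of -0.50 and -0.24, each with an adjusted p of 0.96; without the doubly deposited library the Chrm2 difference was -0.32. Of the 23 measured cholinergic genes, 0 passed over all genes and 0 when adjusted over the list alone. Their median difference was -0.25, with a camera adjusted p of 0.019 and an adjusted p = 0.94 with an estimated correlation. Without the doubly deposited library, whose mean level of 1.382 lay below the 2.285 to 2.789 of all others, the median was -0.10 and the preset call was lost (0.23).

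Altogether 13 of 39 lists passed camera with the preset correlation, 0 with an estimated correlation and 0 with fry. The adjusted p = 0.94 with an estimated correlation applies to each of them, and each held 0 called genes. Lower lists were the GABA interneuron genes (median -0.37, camera adjusted p 0.012), the neuropeptides that modulate transmission (-0.42, 0.0073), excitatory cortical neuron genes (-0.26, 0.022), potassium channels (-0.13, 0.048), synaptic vesicle proteins (-0.05, 0.042), microglial genes (-0.14, 0.022), striatal markers (-0.41, 0.022), olfactory bulb markers (-0.89, 3.5e-06) and heat shock genes (-0.09, 0.00059). Higher lists were the interferon-induced genes (0.13, 0.013), the myelin genes of mature oligodendrocytes (0.17, 0.0033) and the choroid plexus markers (0.44, 0.0094). Without the doubly deposited library the calls for interneurons (median -0.05), neuropeptides (0.04), excitatory neurons (0.05), potassium channels (-0.02), synaptic vesicles (-0.0023), striatal markers (-0.14), myelin genes (0.11) and choroid plexus (0.15) were lost as well, and 7 lists passed the preset test. These were microglia, whose median was then 0.09, interferon (0.16), olfactory bulb (-0.69), cytosolic ribosomal proteins (0.04), heat shock (-0.07), glucocorticoid-induced genes (-0.07), and the mitochondrially encoded genes, whose median was 0.08 and mean -0.12. None of the 7 held with an estimated correlation (adjusted p = 0.91) or with fry (0.93).

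Several other lists close to the study's subject were not called in dTg against Ct. The 35 reported miR-211 targets had a median of -0.03 (camera adjusted p 0.25). The 43 TGF-beta pathway genes had a median of 0.00 (1.0), the 43 activity-regulated genes -0.13 (0.44; 0.03 without the doubly deposited library), and the 50 genes in which mutations cause epilepsy -0.01 (0.48). GABA receptor genes had a median of -0.04 but a mean of 0.01, and glutamate receptor genes a median of -0.05. An 8mer site in a 3'UTR is the strongest kind of match to a microRNA and usually lowers the transcript slightly. The 1085 genes with an 8mer site for miR-211-5p were shifted by 8.5e-06 relative to the 8689 without a site, at a camera p of 0.74 with the preset and 0.80 with an estimated correlation. The median difference of the site genes, -0.0025, lay at percentile 85.1 of the medians of 10000 random lists matched on level and 3'UTR length. With 13 libraries the shift was -0.03116 at a camera p of 0.0061, unadjusted. These left out the doubly deposited library, Ct replicate 2 and dTg replicate 7, a choice made after the data were seen.

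**Figure D1:**
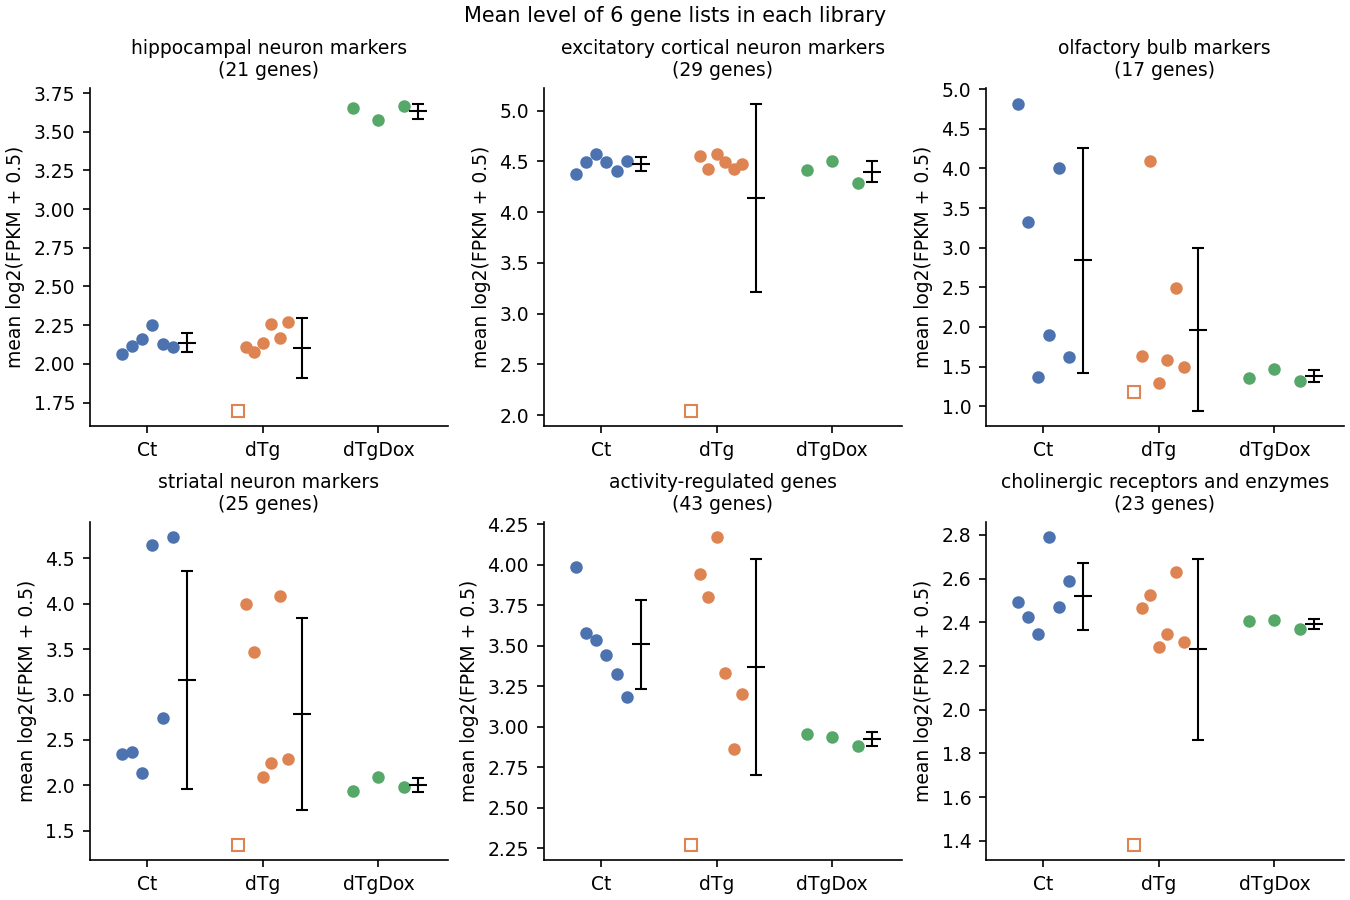
Mean log2(FPKM + 0.5) of 6 gene lists in each library by group; dots are libraries, the open square is the doubly deposited library, and the black bar is mean ± SD. Hippocampal markers lay at 3.573 to 3.668 in dTgDox and at 1.695 to 2.270 in all other libraries.

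The comparison of dTgDox with dTg asked what changed after 4 days of doxycycline, which is meant to switch the transgene off. Here 1537 genes passed, against 0 between dTg and Ct. Of 21 markers of hippocampal neurons 10 rose, the astrocyte filament Gfap rose, and 51 of 87 ribosomal protein genes rose, a list call that was lost at adjusted p = 0.55 with an estimated correlation. Genes for sodium and calcium channels, immediate-early responses and the amino-acid stress response included members that fell. Most of these genes differed from Ct in the same direction.

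Of the 1537 genes, 908 rose and 629 fell, which is 8.01% of those tested, with 59.1% of the calls higher; 325 changed at least 2-fold and 1254 were protein-coding. At the unadjusted level limma gave 4348 genes. Without the doubly deposited library 3596 passed, 1839 higher and 1757 lower, including 907 of the 908 and all 629. No rescaling of the libraries tried moved the share of higher calls by more than 10 percentage points. In the count of genes changed, dTgDox against dTg, leaving out dTgDox replicate 1, 2 or 3 gave 492, 726 and 569. No gene was called both here and in dTg against Ct. The covariance across genes of the fold changes of these comparisons was -0.028, where -0.0327 came from simulated data with no group effects because both use the dTg mean. With the dTg libraries split between the comparisons, the mean covariance was 0.0182 over 35 splits, with a range of 0.0004 to 0.0410; without the doubly deposited library it was 0.0101.

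The largest named increases were in genes of the hippocampal formation. Spink8 (ENSMUSG00000050074, chromosome 9, 109812280 to 109826633), a protease inhibitor of CA1 pyramidal cells, had 2.49 ± 2.14 FPKM (SD, n = 7) in dTg and 47.1 ± 11.5 (SD, n = 3) in dTgDox, a log2 difference of 4.30 (SE 0.54, adjusted p 0.00028). Fibcd1 (ENSMUSG00000026841, chromosome 2, 31813290 to 31846005), a chitin-binding receptor of CA1, rose from 1.83 ± 0.89 to 24.8 ± 1.27 FPKM, a difference of 3.60 (SE 0.40, adjusted p 6.6e-05). C1ql2 (ENSMUSG00000036907, chromosome 1, 120340582 to 120343174), a synapse organiser of dentate mossy fibres, rose from 0.47 ± 0.42 to 30.7 ± 12.0 FPKM, a difference of 5.02 (SE 0.34, adjusted p 5.4e-07). The lactase gene Lct and Prox1, both marks of dentate granule cells, rose by 2.91 and 1.95, and the neuropeptide Y receptor Npy2r and the calcium-binding Cabp7 by 3.41 and 3.17. Gpr161 (ENSMUSG00000040836, chromosome 1, 165295789 to 165326745), a receptor of the primary cilium, rose by 2.64 (SE 0.13, adjusted p 1.6e-08). Klk8, Kcng2, Rasd1, Shisa6 and Pkp2 rose by 2.42 to 2.71. Of the 21 measured hippocampal markers 10 rose and 0 fell over all genes, and 12 rose adjusted over the list alone. Their median was 1.06, and the camera adjusted p of 3.2e-12 held with an estimated correlation (0.001) and with fry (5.2e-09); this was the only list called by all of these tests. Mean list level was 3.573 to 3.668 in the 3 dTgDox libraries, 2.063 to 2.248 in Ct, 2.077 to 2.270 in dTg replicates 2 to 7 and 1.695 in the doubly deposited library.

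Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the filament protein of reactive and hippocampal astrocytes, rose from 34.9 ± 8.84 to 202 ± 74.5 FPKM, a difference of 2.50 (SE 0.31, adjusted p 0.0002). Serpina3n, a protease inhibitor released by reactive astrocytes, rose by 2.75. Both genes were higher in all 3 dTgDox libraries than in every Ct and dTg library. The 26 reactive astrocyte genes as a list did not pass, with a median of -0.01, a mean of 0.23 and a camera adjusted p of 0.17. The astrocyte list passed with a median of 0.17 (camera adjusted p 0.035; adjusted p = 0.76 with an estimated correlation), with Cldn10 among the risen and Aldh1l1 the one that fell. For astrocyte markers, dTgDox against dTg, the adjusted p was 0.054 to 0.087 without dTg replicate 2, 3, 5 or 6 or dTgDox replicate 1 or 2.

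In cholinergic genes, Chrna7 rose from 5.25 ± 1.87 to 10.7 ± 2.54 FPKM, a difference of 1.03 (SE 0.29, adjusted p 0.041), with all 3 dTgDox libraries, at 8.00 FPKM or more, above every Ct and dTg library. The call was close to the threshold: for Chrna7, dTgDox against dTg, the adjusted p was 0.16, 0.059 and 0.195 without dTgDox replicate 1, 2 and 3, and up to 0.067 without single Ct or dTg libraries other than the doubly deposited one. The doubly deposited library had the lowest Chrna7 level in dTg, which enlarged the rise. Against Ct, Chrna7 did not pass in all 16 libraries but passed without the doubly deposited one. The dTgDox libraries also had the higher hippocampal marker level, so the source of the Chrna7 difference could not be separated. Chrm5, the rarest muscarinic receptor, rose by 1.63 from 0.089 ± 0.049 FPKM (adjusted p 3.7e-05). Chrna5, an accessory nicotinic subunit, differed by 1.06 with an adjusted p of 0.058. Ache differed by -0.11 with an adjusted p of 0.64. Of the 23 cholinergic genes 2 rose over all genes and 3 adjusted over the list alone; the median was -0.08, the mean 0.12, and the camera adjusted p 0.72. The mean was -0.02 and the median -0.05 without the doubly deposited library. In the TGF-beta list Tgfb2, a ligand, rose by 1.79 (SE 0.20, adjusted p 8.4e-05). Id2, a transcriptional inhibitor induced by BMP signals, fell by 0.49, the antagonist Nog by 0.57 and Smad1 by 0.39, while Tgfbr2 differed by 0.18 with an adjusted p of 0.55. For Id2 the doubly deposited library was far above the other dTg libraries, which enlarged its fall. Over the 43 genes the median was -0.06 (camera adjusted p 0.55).

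Immediate-early genes report recent neuronal firing. Dusp1, which ends MAP kinase signals, fell by 1.86 (adjusted p 0.015), Ier2 fell by 1.39 (0.034) and Trib1 fell by 1.38 (0.0062), whereas Jun, a transcription factor also of stress and injury, rose by 0.81 (0.035). Without dTgDox replicate 3 each of these 4 calls was lost, with an adjusted p of 0.0794 for Dusp1, dTgDox against dTg, 0.141 for Ier2, dTgDox against dTg, 0.051 for Trib1, dTgDox against dTg, and 0.171 for Jun, dTgDox against dTg. Of the 43 activity-regulated genes 1 rose and 3 fell, and 1 rose and 4 fell adjusted over the list alone. The list passed with a median of -0.32 (camera adjusted p 0.016; adjusted p = 0.76 with an estimated correlation). For activity-regulated genes, dTgDox against dTg, the adjusted p was 0.054 and 0.058 without dTg replicate 2 and 4. Scn1a, the sodium channel whose loss causes Dravet syndrome, fell by 0.77 (adjusted p 0.0049) from 28.8 ± 4.40 to 16.5 ± 0.61 FPKM. Scn2a fell by 0.56, the calcium channel genes Cacnb4 and Cacna1i by 1.07 and 0.76, and Gabrd, the extrasynaptic GABA receptor subunit, by 1.56 (adjusted p 0.018). The doubly deposited library was far above the other dTg libraries for Gabrd, which enlarged its fall. The sodium, calcium and HCN channel list had a median of -0.23 (camera adjusted p 0.016; adjusted p = 0.55 with an estimated correlation), with 0 higher and 5 lower, or 2 and 8 adjusted over the list alone. The epilepsy list had a median of -0.17 (0.0044; adjusted p = 0.76 with an estimated correlation), with 8 genes lower, or 10 adjusted over the list alone.

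Of 87 measured ribosomal protein genes, 51 rose and 0 fell over all genes and 78 rose adjusted over the list alone, with a median of 0.37 and a camera adjusted p of 5e-33. The call was lost with estimated correlation (adjusted p = 0.55 with an estimated correlation) and held with fry (0.0099). Rps3, a protein of the small subunit, rose by 0.42 (adjusted p 0.0033). Values of the near-identical copies Rps3a2 and Rps3a3, at 0.81 and 0.99, are uncertain because they share reads with other copies. Oxidative phosphorylation genes of the nucleus, including Atp5j2 (0.38), Ndufb9 (0.35) and Uqcr11 (0.31), had a median of 0.11 with 11 higher and 0 lower, or 12 and 1 adjusted over the list alone (camera adjusted p 1.3e-06; adjusted p = 0.76 with an estimated correlation). Mitochondrial ribosomal genes such as Mrpl11 and Mrpl27 had a median of 0.09 with 10 higher, or 13 adjusted over the list alone (0.00021; adjusted p = 0.58 with an estimated correlation; fry 0.034).

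Another 9 lists passed camera, none of them with an estimated correlation. Adjusted p = 0.76 with an estimated correlation applies to all but the circadian list, for which it was 0.58. Clock genes had a median of -0.34 (camera adjusted p 0.0017), where Cry2, a repressor of the clock, and Arntl, its activator, each fell by 0.38. Stress-response genes driven by ATF4 had a median of -0.18 (0.016): Atf4 itself fell by 0.43, the chromatin regulator Nupr1 by 1.24, the tRNA synthetase Cars by 0.72 and the arginine carrier Slc7a1 by 0.46. Myelin genes had a median of 0.63 (1.2e-06), with Anln, a myelin septin scaffold, higher by 1.5. Choroid plexus markers had a median of 0.84 (0.0056), with the hormone co-receptor Kl higher by 2.14. This rested on dTgDox replicate 3, at 3.967 against 1.150 and 1.036 in the others: for choroid plexus markers, dTgDox against dTg, the mean went from 0.94 to 0.011 and the adjusted p was 1.0 without it. Microglial genes (0.37, 0.0056), endothelial genes (-0.16, 0.038), pericyte genes (-0.17, 0.044), blood genes (-0.94, 0.017) and striatal markers (-0.70, 0.016) held 0 called members. The calls for microglia (median 0.12, adjusted p 0.081), blood (-0.89, 0.12) and the stress response (-0.16, 0.087) were lost without the doubly deposited library. Other single libraries also ended calls. For microglia markers, dTgDox against dTg, the adjusted p was 0.066 without dTgDox replicate 1. For endothelial markers, dTgDox against dTg, it was 0.055 to 0.126 without dTg replicate 4, 5, 6 or 7 or dTgDox replicate 1 or 2. For pericyte and smooth muscle markers, dTgDox against dTg, it was 0.054 to 0.239 without dTg replicate 3, 4, 6 or 7 or dTgDox replicate 2. For blood cell markers, dTgDox against dTg, it was 0.062 and 0.058 without dTg replicate 7 and dTgDox replicate 3, and for striatal neuron markers, dTgDox against dTg, 0.059 and 0.104 without dTg replicate 2 and 6. Not called were the miR-211 targets (median 0.02, camera adjusted p 0.94), in which Pou3f2 (ENSMUSG00000095139, chromosome 4, 22482780 to 22488366), a factor of upper-layer cortical neurons, fell by 1.21 (adjusted p 0.0088). Interneuron genes (-0.12, 0.98), potassium channels (-0.20, 0.065) and neuropeptides, with a median of -0.12 and a mean of 0.01, were not called either. Leaving out the doubly deposited library, their medians were -0.24, -0.28 and -0.42, and potassium channels (0.00058), neuropeptides (0.026), synaptic vesicle genes (-0.18, 0.0036) and glucocorticoid-induced genes (0.26, 0.015) passed camera with the preset correlation. In that fit 18 of 39 lists passed with the preset correlation, but only 1 with an estimated correlation and 12 with fry. Genes with an 8mer site were shifted by -0.04 (camera p 0.064 preset, 0.17 estimated, percentile 10.3). Their median of -0.0481 lay within the central range of the matched random lists, -0.0547 to -0.0225.

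Among the largest decreases, AA465934, a noncoding transcript, fell by 3.25 from 76.0 ± 23 to 7.28 ± 1.47 FPKM. It ranged from 5.215 to 93.542 FPKM within Ct, so Ct libraries overlapped both groups. Tnnc1 (ENSMUSG00000091898, chromosome 14, 31208312 to 31211729), a calcium-binding troponin, fell by 2.46 (adjusted p 0.032) from 17.7 ± 10.8 to 2.0 ± 0.40 FPKM, and without dTgDox replicate 3 the adjusted p for Tnnc1, dTgDox against dTg, was 0.135. Hkdc1, a hexokinase, fell by 2.14, the matrix protein Abi3bp and the Ras exchange factor Rasgef1c by 2.10 each, the small heat shock protein Hspb3 by 1.88 and the transcriptional co-activator Cited4 by 1.70. Exph5, Atp6ap1l, Stard8 and Lemd1 fell by 1.95 to 1.74. For Exph5 the doubly deposited library was far above the other dTg libraries, which enlarged its fall, and for Stard8 and Lemd1 far below them.

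**Figure D2:**
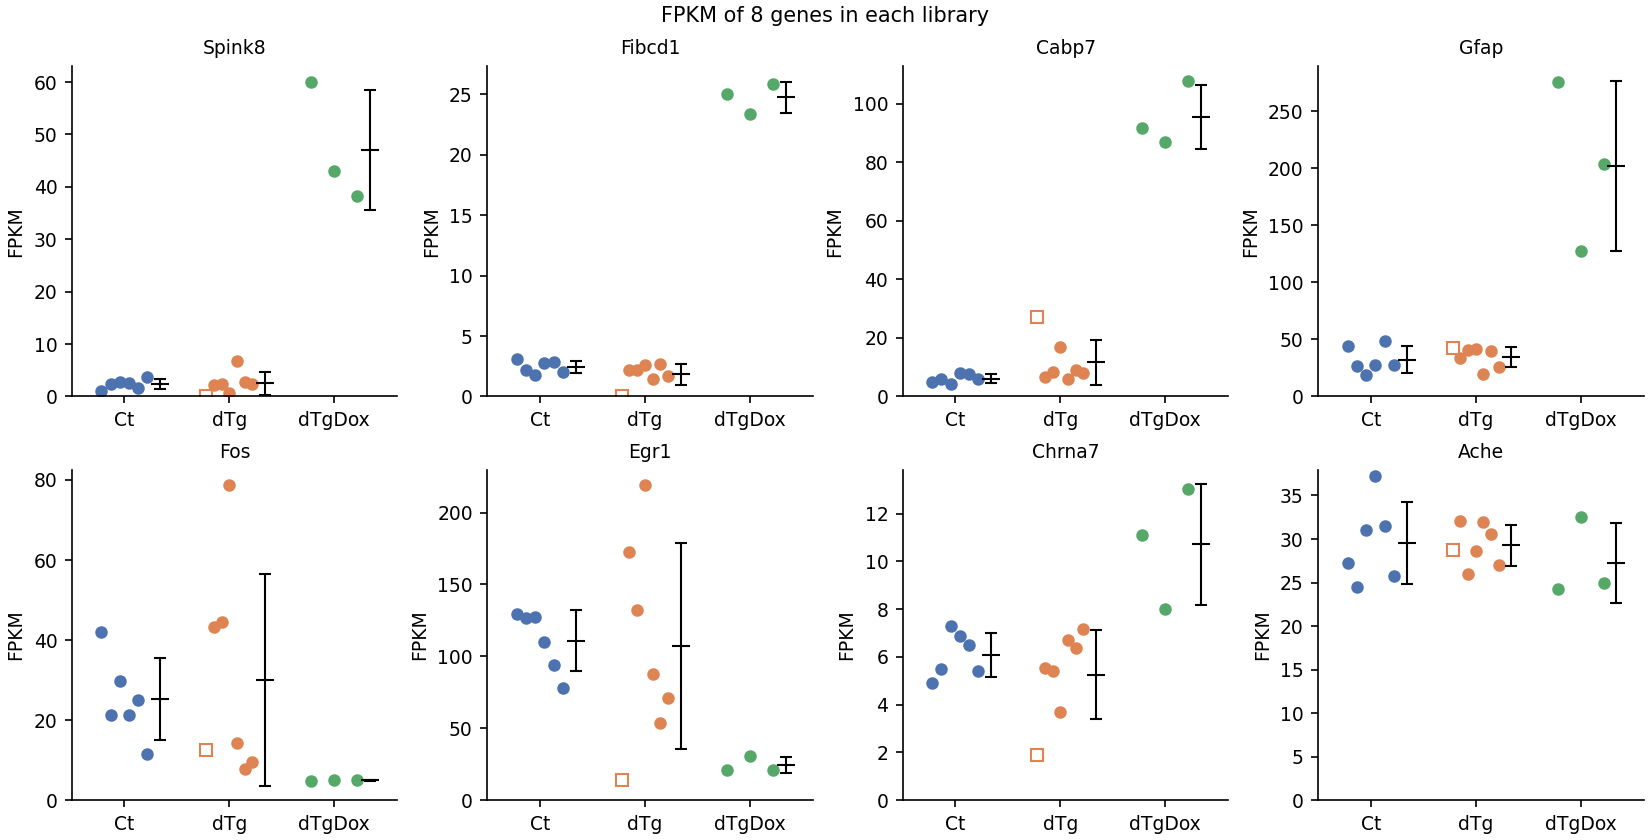
FPKM of 8 named genes in each library by group; dots are libraries, the open square is the doubly deposited library, and the black bar is mean ± SD. Spink8, Fibcd1, Cabp7 and Gfap were higher in all 3 dTgDox libraries than in any other, while Ache overlapped between groups.

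The comparison of dTgDox with Ct asked whether miR-211 mice after the intended transgene shut-off resembled driver-only mice. Between these libraries 1504 genes passed, and most were also called against dTg in the same direction. Gfap, 10 of 21 hippocampal markers and 49 of 87 ribosomal protein genes were again higher, the ribosomal list with adjusted p = 0.55 with an estimated correlation. Fos and Egr1, whose transcription follows neuronal firing within minutes, were lower. Since no Ct mice received doxycycline, transgene shut-off, the drug and any other difference of the dTgDox libraries, such as their hippocampal marker level of 3.573 to 3.668 against at most 2.270 elsewhere, could not be separated.

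Of the 1504 genes 853 were higher and 651 lower, which is 7.84% of those tested; 357 differed at least 2-fold and 1227 were protein-coding. At the unadjusted level limma gave 4313. Without the doubly deposited library 3758 passed, 1880 higher and 1878 lower, including all 853 and all 651. In the count of genes changed, dTgDox against Ct, leaving out dTgDox replicate 1, 2 or 3 gave 552, 745 and 614. Shared with the comparison against dTg were 684 higher and 451 lower genes, and 0 genes were opposite; both comparisons use the same dTgDox libraries, so some sharing arises without a group effect. The covariance of the fold changes was 0.194 against 0.0760 in simulated data with no group effects, and the dTgDox libraries were too few to split.

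C1ql2 was higher by 5.20 (adjusted p 6e-07), Spink8 by 4.11 (0.00049), Cabp7 by 3.89 (2.1e-05), Fibcd1 by 3.12 (0.00034), Npy2r by 3.03, Shisa6 by 2.83, Lct by 2.72 and Gpr161 by 2.64. Rps2-ps13 and Rps2-ps10, pseudogenes of a ribosomal gene, had differences of 3.05 and 2.85 that are uncertain because of shared reads. Of the 21 hippocampal markers 10 were higher over all genes and 11 adjusted over the list alone, with a median of 1.19 (camera adjusted p 4.5e-11, 0.0016 with an estimated correlation, fry 1.6e-08). Gfap was higher by 2.63 (SE 0.31, adjusted p 0.00016), Prox1 by 2.29, the vesicle protein gene Doc2b by 2.30, Kl by 2.78 and Tgfb2 by 1.93 (adjusted p 5.3e-05). Chrna7 differed by 0.76 (SE 0.30) with an adjusted p of 0.14, and of 0.01 without the doubly deposited library. Chrm5 was higher by 1.47, Ache differed by -0.11 (adjusted p 0.67), and Tgfbr2 by 0.18 (0.57). Cholinergic genes had a median of -0.13 (camera adjusted p 0.63) with 1 called, and TGF-beta genes -0.05 (0.52).

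Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) fell by 2.16 (SE 0.61, adjusted p 0.042) from 111 ± 21.2 FPKM (SD, n = 6) in Ct to 24.4 ± 5.58 (SD, n = 3). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) fell by 2.14 (SE 0.63, adjusted p 0.0498) from 25.2 ± 10.2 to 4.93 ± 0.18 FPKM. All 3 dTgDox libraries lay below every Ct library in both. Neither call held without a dTgDox library: leaving out replicate 1, 2 and 3 gave adjusted p of 0.155, 0.089 and 0.153 for Egr1, dTgDox against Ct, and 0.159, 0.133 and 0.153 for Fos, dTgDox against Ct. Dusp1 fell by 1.71 and Trib1 by 1.34, and Jun was higher by 1.10. Activity-regulated genes had a median of -0.60 with 1 higher and 4 lower, or 1 and 8 adjusted over the list alone (camera adjusted p 0.0027; adjusted p = 0.67 with an estimated correlation). Kcnh1, a potassium channel linked to epilepsy, fell by 1.10 (adjusted p 0.0004), Hcn4, a pacemaker channel, by 1.10, Scn1a by 0.70 and Slc12a5, the chloride exporter that makes GABA inhibitory, by 0.48. Medians of -0.35 for the sodium, calcium and HCN channels (0.0036; adjusted p = 0.41 with an estimated correlation), -0.30 for potassium channels (0.004; adjusted p = 0.58 with an estimated correlation) and -0.19 for epilepsy genes (0.00077; adjusted p = 0.58 with an estimated correlation) passed camera. Synaptic vesicle genes passed with -0.16 (0.0064; adjusted p = 0.67 with an estimated correlation).

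In all 17 lists passed camera, 1 with an estimated correlation and 2 with fry. Ribosomal protein genes had a median of 0.36 with 49 higher and 0 lower, or 76 adjusted over the list alone (2.1e-32; adjusted p = 0.55 with an estimated correlation; fry 0.012). Myelin genes had a median of 0.81 with 3 higher, or 21 adjusted over the list alone (5.8e-10; adjusted p = 0.63 with an estimated correlation); Anln, Ermn and the oligodendrocyte factor Myrf were the 3, at 1.59, 1.23 and 0.83. Astrocyte genes had a median of 0.12 (0.0046; adjusted p = 0.63 with an estimated correlation), and clock genes -0.30 (0.0036; adjusted p = 0.58 with an estimated correlation). Stress-response genes had a median of -0.17 (0.004; adjusted p = 0.62 with an estimated correlation), where Chac1, which degrades glutathione, and Nupr1 fell by 0.79 and 1.18. Adjusted p = 0.67 with an estimated correlation applied to choroid plexus (median 1.16, 9.3e-05), blood (-1.04, 0.012), striatal (-1.18, 0.0006), olfactory bulb (-1.41, 0.0008) and oxidative phosphorylation genes (0.14, 1.6e-06). For choroid plexus markers, dTgDox against Ct, the mean went from 1.43 to 0.498 and the adjusted p was 0.18 without dTgDox replicate 3. For blood cell markers, dTgDox against Ct, the adjusted p was 0.071 without the doubly deposited library and 0.0501 without dTgDox replicate 3. Neuropeptides (-0.54, 0.032) and microglial genes (0.18, 0.0025) passed camera with the preset correlation against Ct without the doubly deposited library. There 18 of 39 lists passed with the preset correlation, but only 1 with an estimated correlation and 10 with fry. Mitochondrial ribosomal genes had a median of 0.11 (0.0008; adjusted p = 0.58 with an estimated correlation). The miR-211 targets were not called, with a median of 0.03 and a mean of -0.07 (0.64). Olfactory bulb levels varied within Ct and dTg, with means of 4.817, 3.328 and 4.006 in Ct replicates 1, 2 and 5 and 4.092 and 2.492 in dTg replicates 3 and 6, against 1.175 to 1.900 in all others, dTgDox included. Striatal levels were 4.651 and 4.732 in Ct replicates 4 and 6, 3.998, 3.468 and 4.081 in dTg replicates 2, 3 and 6, and 1.345 to 2.737 in all others. Genes with an 8mer site were shifted by -0.05 at a camera p of 0.048, unadjusted among 3 such tests, and 0.147 with an estimated correlation. Their median of -0.0518 lay at percentile 7.69 of the matched random lists. It was within the central range of those lists, -0.0563 to -0.0242, so lists matched on level and 3'UTR length also lay lower. The shift was -0.03227 for the 7mer-m8, a weaker seed match, and -0.03687 for a reversed 8mer that still holds the 6mer core. It was -0.01435 for a shuffled 8mer without the core, the one control free of the seed.

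**Figure D3:**
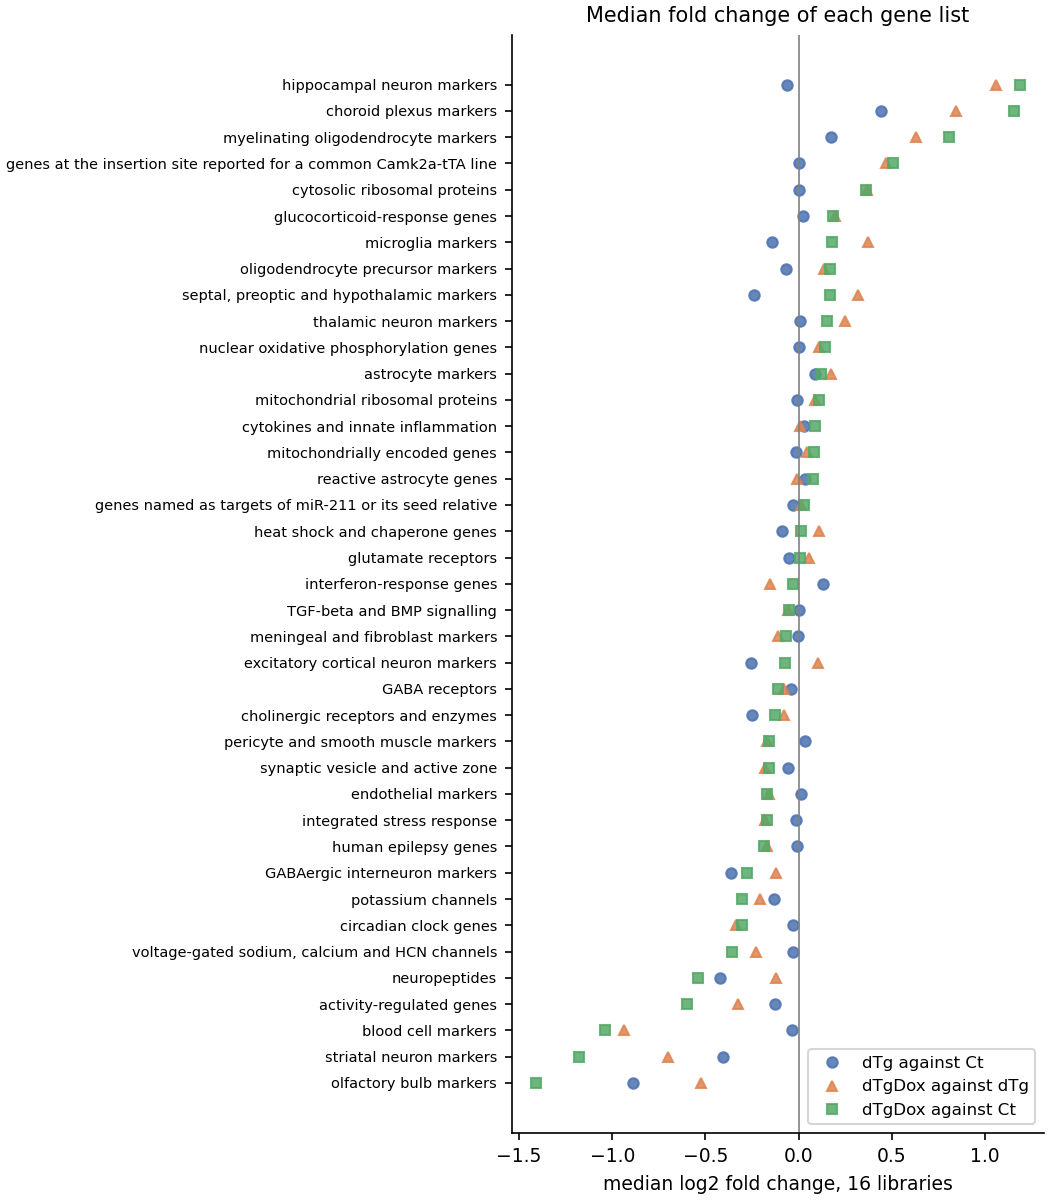
Median log2 difference of each of 39 gene lists in dTg against Ct (circles), dTgDox against dTg (triangles) and dTgDox against Ct (squares). The hippocampal list, at 1.06 and 1.19 in the dTgDox comparisons, was the one list called with an estimated correlation.

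Genes at a reported insertion site of a Camk2a driver line on chromosome 12 were followed because the labels give the driver to every group but NTg. The region from 116206262 to 117276849 holds Wdr60, a dynein subunit of cilia, Esyt2, a membrane tether, Ncapg2, a condensin subunit, and Ptprn2, a secretory granule phosphatase; Vipr2, a receptor of vasoactive intestinal peptide, starts at 116077726. Esyt2 had 6.31 ± 1.83 FPKM (SD, n = 6) in Ct, 7.77 ± 3.55 (SD, n = 7) in dTg and 11.4 ± 1.12 (SD, n = 3) in dTgDox. By library it had 9.99 in Ct replicate 2, 12.4 in dTg replicate 7, 13.5 in the doubly deposited library and 5.16 to 6.13 in the other Ct and dTg libraries. Its difference of 0.83 between dTgDox and Ct had an adjusted p of 0.091, and of 0.021 without the doubly deposited library. Ptprn2 had 90.3 FPKM in Ct replicate 2 and 98.2 in dTg replicate 7, against 74.5 ± 3.27 in dTgDox and group means of 50.7 in Ct and 50.6 in dTg. Wdr60 had 5.11 and 4.92 FPKM in those libraries and 4.21 ± 0.13 in dTgDox. Vipr2 fell by 2.64 in dTgDox against Ct (adjusted p 0.044), with 1.37 FPKM in Ct replicate 2 and 0.30 in dTg replicate 7; for Vipr2, dTgDox against Ct, the adjusted p was 0.158 without dTgDox replicate 1.

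**Figure D4:**
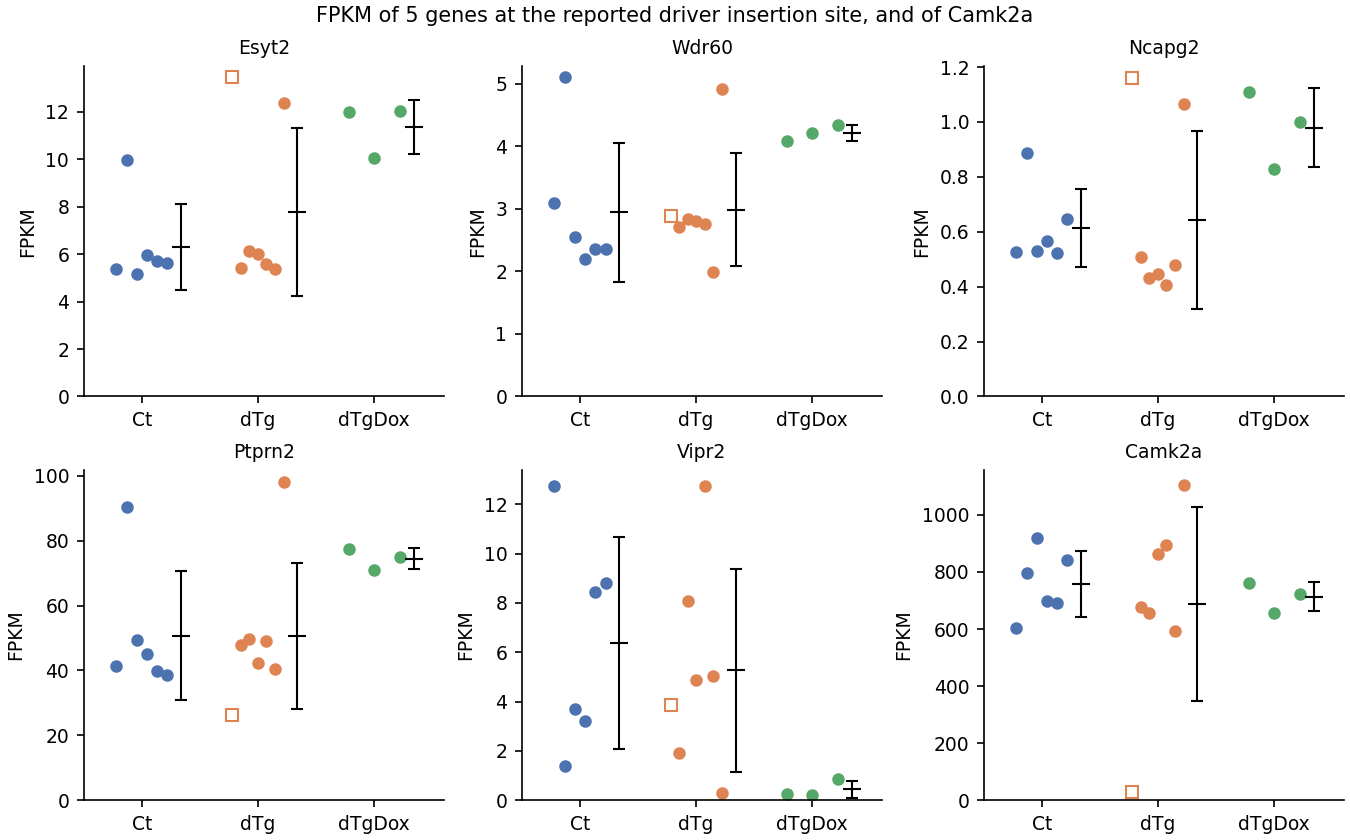
FPKM of 5 genes at the reported insertion site and of Camk2a in each library by group; dots are libraries, the open square is the doubly deposited library, and the black bar is mean ± SD. For Ptprn2, Ct replicate 2 and dTg replicate 7 had 90.3 and 98.2 FPKM.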

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

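The tests on other splits of the samples were fixed before their results were seen; the tests on cerebellar tissue, depth, hippocampal tissue, cortical neuron share, an App transgene and the insertion site were chosen after the result was seen. In each group of 6 or 7 libraries the gap between an extreme library and its nearest neighbour, divided by the whole range, was compared with Dixon's critical values of 0.625 and 0.568. Of 500 groups tested, 87 exceeded them; chance gives about 1 in 20, or 25. The doubly deposited library accounted for 65 and other libraries for 22. The dTgDox group was too small for this test.

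The doubly deposited library was the lowest of the dTg group for genes of cortical and hippocampal neurons and other called genes: Camk2a (gap over range 0.83), the scaffold Homer1 (0.758), the factor Bcl11b (0.731), Crym (0.759), Rprm (0.932), the potassium channel genes Kcna4 (0.617), Kcnab2 (0.786) and Kcng2 (0.671), the vesicle GTPase Rab3a (0.688), Fibcd1 (0.715), Npy2r (0.783), Klk8 (0.585), Chrna5 (0.748), Pou3f2 (0.847), Hspb3 (0.769), Lemd1 (0.645), Rasgef1c (0.69), Stard8 (0.595), Hkdc1 (0.625) and Serpinb8 (0.641). It was also the lowest for interneuron and striatal genes Dlx6 (0.63), Adcy5 (0.582), Meis2 (0.624), Pde1b (0.7) and Tac1 (0.578), for Runx2 of the miR-211 target list (0.71), for the microglial genes Cd53 (0.897), P2ry13 (0.736), Tmem119 (0.84), Cd68 (0.634), Ly86 (0.779), Trem2 (0.844) and Tyrobp (0.803), and for the immunoglobulin gene Ighg2c (0.655). Lists with their lowest mean in it were the cholinergic genes (0.723), miR-211 targets (0.644), interneurons (0.733), sodium, calcium and HCN channels (0.658), potassium channels (0.892), epilepsy genes (0.629), excitatory cortical neurons (0.941), synaptic vesicles (0.675), neuropeptides (0.804), microglia (0.925), cytokines (0.593), oligodendrocyte precursors (0.888), hippocampal markers (0.664) and plaque-associated microglia (0.648). It was the highest for the choroid genes Folr1 (0.749), Otx2 (0.583) and Sostdc1 (0.618), for Neurod2 (0.631), Ephb2 (0.614), Stat2 (0.755), Shisa6 (0.707), Nos1 (0.75), Prox1 (0.811), Dvl3 (0.592), Gabrd (0.763), Id2 (0.831), Exph5 (0.711), Slc14a1 (0.852) and Doc2b (0.614), and for the thalamic (0.665) and cerebellar lists (0.849).

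In data outside the comparisons, the file labelled NTg had a mean log2 level of 7.085 for cerebellar markers, against 1.407 to 1.849 in Ct; these are the values of the doubly deposited library. Of 20 measured cerebellar markers, 18 lay above 5 times the highest of the other 15 libraries. The most abundant were Pcp2, a Purkinje cell protein, at 661 FPKM against at most 6.15 elsewhere, Car8 at 455 against 7.47, Cbln3 at 447 against 4.72, Cbln1 at 437 against 10.2, and Gabra6, a granule cell receptor subunit, at 430 against 4.10. Members of this list that also occur in other lists include Calb1, Zic1 and Gabra6, and the cortex expresses Calb1 and Itpr1. Cerebellar tissue is a candidate source of this library, since Camk2a, abundant in cortex, was at 28.3 FPKM. Low sequencing depth was excluded, as its relative depth was 1.02 within the range of 0.87 to 1.25. A wrong file under the dTg label, a wrong dissection and an animal of either genotype stay open, because a single library cannot separate them, and no biological explanation was tested.

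The large number of changed genes in dTgDox was weighed next. Hippocampal tissue in these libraries is a candidate explanation: 10 of 21 hippocampal markers were higher against Ct and 0 lower, with marks of CA1 and of the dentate gyrus both present. A lower share of cortical neurons that raises all other markers alike could not be excluded. Olfactory bulb markers moved by -1.409 and striatal markers by -1.176 while hippocampal markers moved by 1.185. However, olfactory bulb and striatal levels varied widely within Ct, at 1.37 to 4.817 and 2.131 to 4.732. In dTgDox they were 1.323 to 1.469 and 1.942 to 2.089, near the lowest Ct libraries. Neither list call held with an estimated correlation. An App transgene with plaque-associated microglia is another candidate explanation, since App had 904 to 1268 FPKM in dTgDox and 428 to 581 in Ct and 7 of 19 plaque-associated genes were higher against Ct and 0 lower, or 10 adjusted over the list alone. It could not be decided. The list's camera adjusted p of 4.6e-06 became adjusted p = 0.097 with an estimated correlation, and read sequences were not used here. Outside that list, Prnp, whose promoter and 3'UTR serve in several App transgenes, had 1095 to 1688 FPKM in dTgDox and 356 to 473 in Ct. The neighbouring pseudogene Lamr1-ps1 had 13 to 18.6 FPKM in dTgDox and 0 in Ct. Both were chosen after their values were seen. Doxycycline, loss of miR-211 and a separate source or batch of these mice stay open and untested, since all are confounded with the group.

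The third pattern was in genes at the reported driver insertion site. Within Ct, replicate 2 was far above the others for Esyt2 (gap over range 0.783), Ncapg2 (0.629) and Ptprn2 (0.705), and within dTg, replicate 7 was far above for Wdr60 (0.607). The mean log2 level of these 4 genes, which were picked after their values were seen, was 3.2144 in Ct replicate 2, 3.3494 in dTg replicate 7 and 3.051 to 3.2035 in dTgDox, against 2.2994 to 2.5023 in the other libraries labelled Ct or dTg except the doubly deposited one, at 2.7602. Vipr2, the fifth gene listed beforehand, went the other way. It was lower in Ct replicate 2, dTg replicate 7 and the dTgDox libraries than in every other library. The mean of all 5 was 2.345 to 2.634 in dTgDox and 2.324 to 2.753 in Ct. Opposite movements cancel in that mean, so it cannot test whether these libraries stand apart. A copy-number difference limited to the region, such as a driver insertion with a deletion, may explain the 4 genes but was not decided: in dTgDox against Ct the 5 genes had a median of 0.5042 and 49 flanking genes within 5 megabases -0.06649, a difference of 0.5707, while 1 of the 5, Vipr2, was called lower. For the dTgDox libraries it cannot be told apart from hippocampal tissue, because their lowest marker level, 3.573, lay 1.303 above the highest of the others, 2.27, and no library of another group lies in that range. Ct replicate 2 and dTg replicate 7 had similar levels of the 4 genes at hippocampal marker levels of only 2.115 and 2.27. For those libraries these values argue against hippocampal tissue as the source. The labels of Ct replicate 2 and dTg replicate 7 were not tested further, and no biological explanation was tested.

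Other single libraries stood out as well, near the number that chance gives. In Ct these were Jun (0.655, replicate 1 high), the choroid transport protein Ttr (0.71) and the choroid list (0.632), both high in replicate 6, Cox8b (0.638, replicate 6 high), Xaf1 (0.706) and Ly6a (0.794), interferon-induced genes low in replicate 2, Ndufb2 (0.697, replicate 2 high), Cldn10 (0.636, replicate 5 high), Pou3f2 (0.677) and Ighg2c (0.648), high in replicate 3, C1ql2 (0.791, replicate 4 high) and the mitochondrially encoded list (0.663, replicate 1 low). In dTg they were Chrna10 (0.586) and Tshz1 (0.598), high in replicate 3, the chaperone Hspa5 (0.608) and the heat shock list (0.613), high in replicate 2, Smad3 (0.584, replicate 7 high) and Mrpl3 (0.616, replicate 4 low).

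Other splits of the same libraries were fitted to ask whether chance can be excluded as the source of each result. For dTgDox against dTg, 1 of 100 splits, the real one, gave as many genes, with 1537 called and 1033 in the highest other split, which grouped the doubly deposited library with 2 dTgDox libraries. For dTgDox against Ct, 1 of 84 gave as many, with 1504 called and at most 5 in the others. The real split gave the most genes in both. Shares of 1 in 100 and 1 in 84 are the smallest these splits can give, so chance is unlikely but not excluded. In dTg against Ct, 100 of 100 splits gave as many genes as the real 0, with up to 5 in another split, and 100 of 100 gave an 8mer shift as large as 8.547e-06, with up to 0.04136; real values at or near 0 fix these counts, so they test nothing. For the list counts and the other shifts, splits other than the real one gave results as large, so chance stays a possible source there. In dTg against Ct, 56 of 100 splits gave as many lists as the real 13, with up to 21. Lists as many as 17 came from 21 of 100 splits of dTgDox and dTg, with up to 24, and from 22 of 84 of dTgDox and Ct, with up to 20. A shift of the 8mer genes as large as 0.04247 came from 15 of 100 splits of dTgDox and dTg, with up to 0.07316, and one as large as 0.05107 from 5 of 84 splits of dTgDox and Ct, with up to 0.06502.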

How the results depend on the processing

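The replicate block, the filter, the number of groups fitted, the 7mer-m8 and reversed sites, the UTR choice, the estimated correlation and fry for gene lists, and leaving out single libraries were planned; the tests with the shuffled site, the estimated correlation for the 8mer genes, other pseudocounts, scaling, quality weights, a residual component, gene classes, a stricter filter, limma without trend or robust fitting and 13 libraries were chosen after the result was seen. Among named-gene results that passed in the main fit or in the alternative, none changed direction. Direction was not compared where a gene passed in neither. With scaling by median ratios 295 gene results kept their side of the threshold, 2 became called and 2 were lost. Quantile normalization gave 293, 4 and 2, a pseudocount of 0.1 gave 297, 1 and 1, and a pseudocount of 1 gave 291, 3 and 5. The replicate block lost 65 and added 2, fitting only the 2 groups lost 28 and added 13, no filter lost 16, and 13 libraries lost 2 and added 28. Quality weights added 43 and the residual component 42. Leaving out 1 library kept 4378, lost 332 and added 56.

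For genes changed, dTg against Ct, the count of 0 became 1 with pseudocount 0.1 and 436 with the residual component, and was 0 to 1 with a library left out. For genes changed, dTgDox against dTg, the count of 1537 became 724 with only the 2 groups compared, 541 with the replicate block, 4674 with quality weights, 4165 with the residual component and 2988 with 13 libraries. It was 492 to 3596 with a library left out: 492, 726 and 569 without dTgDox replicate 1, 2 and 3, and 3596 without dTg replicate 1. For genes changed, dTgDox against Ct, the count of 1504 became 3419, 608, 4868, 3930 and 3449 in the same order, and 552 to 3758 with a library left out: 552, 745 and 614 without dTgDox replicate 1, 2 and 3, and 3758 without dTg replicate 1. For genes called in both comparisons, dTg against Ct and dTgDox against dTg, the residual component gave 275. That component was built from the residuals and leaves fold changes as they were, so its construction explains its higher counts. Fewer samples, or removal of the doubly deposited library, are part of the other settings, and the cause was not tested. The numbers in the labels were not found to pair samples: correlations of same-number residuals were -0.145 to 0.105.

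For gene lists called, dTg against Ct, the count of 13 became 3 with quality weights, 7 with 13 libraries, 0 with the estimated correlation, 0 with fry and 7 to 13 with a library left out, 7 without dTg replicate 1. For gene lists called, dTgDox against dTg, 17 became 1 with the estimated correlation and 3 with fry, and was 14 to 18 with a library left out; for gene lists called, dTgDox against Ct, 17 became 1 and 2, and was 16 to 20.

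Means of some lists changed direction. With 13 libraries these were activity-regulated genes, dTg against Ct, 0.1265 (adjusted p 0.029), excitatory cortical neuron markers, dTg against Ct, 0.02237, microglia markers, dTg against Ct, 0.08964, neuropeptides, dTg against Ct, -0.04379, by the direction of the test, and neuropeptides, dTgDox against dTg, -0.3436. Quality weights gave microglia markers, dTg against Ct, 0.05185. With a library left out, the ranges in dTg against Ct were -0.0355 to 0.03058 for cytosolic ribosomal proteins, -0.4071 to 0.01509 for excitatory cortical neurons, -0.2128 to 0.09332 for microglia, -0.229 to -0.004953 for mitochondrially encoded genes, dTg against Ct, whose test pointed up without dTg replicate 1 (-0.1151), and -0.5036 to -0.09461 for neuropeptides. Neuropeptides, dTgDox against dTg, ranged from -0.3016 to 0.1074. The meningeal and fibroblast markers, dTgDox against dTg, ranged from -0.23 to 0.4379, and meningeal and fibroblast markers, dTgDox against Ct, from -0.219 to 0.4489, the highest without dTgDox replicate 2. The microglia and excitatory values, and the test of the neuropeptides, changed direction without dTg replicate 1, and the ribosomal ones without Ct replicate 3 or dTg replicate 6; the cause was not tested.

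For the median shift of genes with a miR-211-5p 8mer site, dTg against Ct, 13 libraries gave -0.03116 (p 0.0061), and a library left out -0.009337 to 0.01161. For the median shift of genes with a miR-211-5p 8mer site, dTgDox against dTg, all annotated UTRs gave -0.05306 (p 0.040), and a library left out -0.05476 to -0.03082, past the threshold without dTg replicate 2 (p 0.032), dTgDox replicate 1 (0.041) or dTgDox replicate 3 (0.025). For the median shift of genes with a miR-211-5p 8mer site, dTgDox against Ct, the call was lost with no filter (-0.02658), the block (-0.05279), quantile normalization (-0.04914), the estimated correlation (-0.05107), and at the 7mer-m8, a weaker seed match (-0.03227), the reversed site, which holds the 6mer core (-0.03687), and the shuffled site, which does not (-0.01435). A library left out gave -0.06918 to -0.03283, lost without Ct replicate 1, 4 or 5 or dTgDox replicate 2. The cause was not tested.

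For the covariance of fold changes, dTg against Ct with dTgDox against dTg, alternatives gave -0.04759 with the block, -0.05498 and -0.0195 with pseudocounts 0.1 and 1, -0.02217 with quality weights, -0.01213 in protein-coding genes, -0.01256 at a mean log2 value of at least 3, and -0.03998 to -0.02234 with a library left out. With the dTg libraries split between the comparisons it was 0.01821; the shared dTg mean alone gave -0.0327 in simulated data.

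Planned count-based fits and normalizations, count filters and the fit with NTg added to Ct were not run, the first because the values are FPKM and the last because the NTg file analysed holds no values of its own. Estimated depth limits genes with few reads; intervals from counts could not be given.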

Other observations

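The tests of the values given here were all chosen after the result was seen, as were the genes. App (chromosome 16, 84949685 to 85173766), the amyloid precursor gene, was higher by 1.12 in dTgDox against Ct (SE 0.15, adjusted p 0.00048). Prnp (chromosome 2, 131909928 to 131938429), the prion protein gene, whose promoter and 3'UTR serve in several App transgenes, had 404 ± 41.3 FPKM (SD, n = 6) in Ct and 1330 ± 315 (SD, n = 3) in dTgDox, a difference of 1.70 (adjusted p 4.2e-06). Lamr1-ps1 (chromosome 2, 131904086 to 131904959), a pseudogene next to Prnp, was listed at 0 in every library labelled Ct, dTg or NTg and had 13 to 18.6 FPKM in the 3 dTgDox libraries. Nr3c2, the mineralocorticoid receptor abundant in hippocampus, was higher by 1.56 in dTgDox against Ct (adjusted p 1.3e-06). Cst7 and Clec7a, genes of microglia around plaques, were higher by 2.88 (0.00067) and 1.45 (0.019). They varied widely, with Cst7 at 13.1, 1.295 and 4.856 FPKM and Clec7a at 4.325, 0.506 and 1.121 FPKM in dTgDox replicates 1, 2 and 3. The plaque-associated list was at 4.858, 3.975 and 4.394 in these replicates, with replicate 2 close to the Ct libraries, at up to 3.911. Of genes of cortical excitatory neurons and interneurons, Lamp5 and Mef2c differed by -1.54 and -2.14 in dTgDox against Ct in the 15 libraries without the doubly deposited one (adjusted p 0.0083 and 1.1e-06), and were not called in all 16. Fezf2, of deep-layer excitatory neurons, was at 16.1 FPKM against 11.35 in Ct (0.53, adjusted p 0.0998 in the 15 libraries), and the excitatory cortical list was at 4.287 to 4.502 in dTgDox and 4.38 to 4.569 in Ct.

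The cerebellar markers as a list had a median of 0.68 in dTg against Ct (camera adjusted p 9.1e-07; adjusted p = 0.44 with an estimated correlation; 0.05 and 0.06 without the doubly deposited library), -0.83 in dTgDox against dTg (0.034; adjusted p = 0.60 with an estimated correlation; -0.21 and 0.99 without the doubly deposited library) and 0.06 in dTgDox against Ct (0.89). The plaque-associated microglia genes had a median of -0.07 in dTg against Ct (0.25). Their median was 0.61 in dTgDox against dTg, with 8 of 19 higher, or 12 adjusted over the list alone (4.4e-07; adjusted p = 0.066 with an estimated correlation), and 0.61 in dTgDox against Ct (4.6e-06; adjusted p = 0.097 with an estimated correlation).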
